A study of Mus musculus with 12 samples.

How the data were processed

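Total RNA of freshly isolated mouse liver cells was purified, labelled with biotin and hybridised to 12 Illumina bead arrays, per the labels' protocols. The deposited table gives an average bead signal intensity per probe and array, per the file headers; its values are linear and, with a lowest value of 30.6, not background subtracted. It also gives a detection p-value per probe and array, per the file headers. A second deposited table holds a normalized intensity per probe; the method of that normalization is not given in the sources used here, and the medians of its columns ran from 48.2 to 49.1. Each of its columns had a Spearman rho of at least 0.9846 with the signal of its own array. All 12 arrays were used and 0 data columns stayed unmapped. Probes detected per array ran from 15354 to 19482.

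The signal was background corrected with normexp, the background being inferred from the detection p-values, with an offset of 16, then quantile normalized over the 12 arrays and taken to log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p below 0.05 on at least 3 of the 12 arrays were kept, 19670 in number. Gene names came from the platform's annotation, updated by gene ID through a RefSeq table of assembly GRCm38.p6, which was used for names only. Of 45281 probes 34885 had 1 gene, 18 several and 10378 were not listed; 34807 IDs were found in the RefSeq table. A gene was represented by its probe with the highest mean over all arrays, which left 10641 genes; among genes with several probes, 67 had probes called both ways in the HCC comparison and 0 in the aggregate comparison. No genome coordinates were used.

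Each gene was fitted with limma (lmFit and eBayes, 2-sided) with a mean per group over all 12 arrays, and p-values were adjusted by Benjamini-Hochberg over genes, with a call at an adjusted p below 0.05. Values with SE are log2 changes and their standard errors, with 3 arrays per group. Where a gene was not detected on any array of the lower group, its fold is a bound: the mean of the higher group against, per array of the lower group, the higher of the lowest value among detected probes and the gene's own value. Lists of genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 5 measured members, and again with an estimated correlation. The 36 lists, 28 of pathways and 8 of cell type markers, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes; 680 of 741 entries matched a gene on the array.

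For the comparisons within a chip the named genes were the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap, a panel of 12 genes whatever their values (Afp, Gpc3, Cd44, Sox9, Epcam, Ly6d, Il6, Krt19, Lin28b, Ggt1, Cyp2e1, H19), and for each called list up to 4 called members with the largest change. For the difference of these comparisons the 5 largest in each direction were named, and for each comparison across chips the 3 largest in each direction. Predicted genes and clone names were passed over among the largest changes. Probes of near-identical families (Mup, Hba, Hbb, Cyp2b, Cyp2c, Cyp3a, Cyp4a12, Gstm, Serpina1, Saa1 and Saa2) may read copies.

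Replicate numbers are shared between groups in the labels. Deviations from the group mean of same-numbered aggregate and non-aggregate arrays correlated at 0.71, 0.54 and 0.64. All pairs of different numbers were negative, but deviations from a mean of 3 arrays cancel out, so this adds little. Same-numbered arrays of these groups also lie side by side on the chip, so a shared source and a shared position cannot be told apart. For the aggregate comparison the fit with the replicate number as a block is given beside the counts of genes. It is also given beside named genes and lists of that comparison where it changes a call. Alternatives were no background correction, median scaling, cyclic loess, the deposited normalized values, no or a stricter detection filter, each probe by itself, only the groups compared, a log2 change of at least 1, array weights, the replicate block, separate normalization of the chips and leaving out each array. On data simulated for the HCC comparison over 10641 genes, 82% of genes changed by 1 on the log2 scale and 94% of those changed by 2 were called. For the aggregate comparison these were 64% and 94%, with 4.9% false among calls. The simulation drew independent noise with 1 spread per gene in all groups, without replicate pairs or correlated genes. Its rates hold for that setting and were not checked for the measured data. Python 3.11.15 and matplotlib 3.10.9 drew the figures.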

Results

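RNA of liver cells from age-matched male mice of the B6 strain was measured on 12 Illumina bead arrays. Per the labels, HCC had been induced by injection of diethylnitrosamine, a carcinogen that hepatocytes activate. The 4 groups, each of 3 arrays, were normal hepatocytes, hepatocellular carcinoma (HCC) described as fully malignant, and premalignant hepatocytes divided into aggregate and non-aggregate cells. The premalignant cells too came from carcinogen-injected mice, per the labels. Normal hepatocytes and HCC lay on 1 chip and both premalignant groups on the other. Of 45281 probes, a mean of 15753 ± 528 (SD, n = 3) were detected in normal hepatocytes, 18781 ± 687 in HCC, 16708 ± 322 in non-aggregates and 17386 ± 487 in aggregates. Mean signal per array ran from 314 to 403, and 10641 genes were tested. Across genes, group means of aggregates and non-aggregates had a Pearson r of 0.99, and those of HCC and normal hepatocytes 0.898. Labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

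HCC was compared with normal hepatocytes to find the genes that differ between these samples. HCC held far more RNA of oncofetal and tumour marker genes. Gpc3, a heparan sulphate proteoglycan of fetal liver, was at least 147-fold higher (adjusted p = 3.91e-07), Tspan8, a tetraspanin, at least 151-fold (adjusted p = 1.71e-07), and Afp, the fetal serum protein alpha-fetoprotein, at least 54.7-fold (adjusted p = 1.69e-05). Spink1, a trypsin inhibitor formerly named Spink3, rose by 7.82 on the log2 scale (SE 0.61, 226-fold). Akr1c18, a hydroxysteroid dehydrogenase, was at least 110-fold higher, the surface protein gene Ly6d at least 128-fold and Gldn at least 77.4-fold. Cd63, a tetraspanin of late endosomes, rose by 7.31 (SE 0.28) and Cyp2a4, a cytochrome P450 more abundant in female liver, by 7.25 (SE 0.57). In total 5218 genes changed, 2451 higher and 2767 lower in HCC. With only the arrays of these groups in the fit 3868 changed, and with array weights 4295. Among the genes named below, normal hepatocytes had Cyp2b9, Amotl1 and Cdh5 detected on 2 of 3 arrays and Birc5, Ifit2, Abcd2 and Acta2 on 1, and HCC had Hectd2os and Tat on 2 and Cyp2b10 on 1.

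The 8 largest falls named in HCC included enzyme and transporter genes, a growth arrest gene, a non-coding transcript and a pseudogene. Sult2a8, a sulphotransferase, had a log2 change of -5.05 (SE 0.31, 33.2-fold lower). Gadd45g, a growth arrest gene, changed by -4.61 (SE 0.60), Hsd3b5, a steroid dehydrogenase, by -4.31 (SE 0.72), and Cyp4a12b, whose probe may read copies, by -4.42 (SE 0.76). Mfsd2a, a lysophospholipid transporter, changed by -4.24, the non-coding Hectd2os by -4.20, Etnppl by -4.19 and the pseudogene Serpina4-ps1 by -4.16. Cyp2e1, a pericentral cytochrome P450, changed by -1.07 (SE 0.16, adjusted p = 0.000183).

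Lists of liver metabolism moved down in HCC. Of 26 drug-metabolising cytochrome P450 and flavin monooxygenase genes 17 fell and 3 rose (18 and 5 adjusted over the list alone), with a median log2 change of -1.46 and camera adjusted p = 6.54e-05. This was the only list of the HCC comparison whose call held with an estimated correlation (adjusted p = 0.0408). Cyp2b10 (-3.67) and Cyp2c54 (-3.53), whose probes may read copies, Cyp2f2 (-3.12) and the aldehyde oxidase Aox3 (-2.86) moved furthest. Of 25 urea cycle and amino acid breakdown genes 21 fell and 0 rose (23 and 0 adjusted over the list alone; median -1.50), among them Hpd (-3.10), Cth (-3.05), the urea cycle enzyme gene Otc (-2.45) and Tat (-2.28). Their camera adjusted p was 3.25e-08, and adjusted p = 0.178 with an estimated correlation. Of 14 male-biased liver genes 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -2.07, or -1.98 with genes undetected in the lower group held at their bound. Elovl3, a fatty acid elongase, was at least 15.2-fold lower and Cyp4a12a, whose probe may read copies, changed by -3.80. The camera adjusted p was 3.23e-06, and adjusted p = 0.167 with an estimated correlation.

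Bile acid synthesis and transport genes were lower in 10 and higher in 1 of 17 (11 and 1 adjusted over the list alone; median -1.05), with falls in the uptake carriers Slco1a4 (-2.99) and Slco1b2 (-2.33) and in Cyp8b1 (-2.54), and a rise in the export pump gene Abcc2 (1.86). The camera adjusted p was 0.00223, and adjusted p = 0.167 with an estimated correlation. Gluconeogenesis genes fell in 5 of 8 (5 adjusted over the list alone; median -0.87), including G6pc (-3.49), Pck1 (-3.48), Slc37a4 (-1.37) and Fbp1 (-1.11), with camera adjusted p = 0.0258 and adjusted p = 0.191 with an estimated correlation. Fatty acid oxidation genes fell in 12 and rose in 1 of 18 (12 and 1 adjusted over the list alone; median -0.86), with Acot1 at -3.72, Decr1 at -2.26 and Acaa1b at -1.94, while Fgf21, a secreted hormone, rose by 2.98. The camera adjusted p was 0.00194, and adjusted p = 0.22 with an estimated correlation. Beta-catenin targets and pericentral genes fell in 10 and rose in 1 of 16 (11 and 1 adjusted over the list alone; median -0.99), with Oat (-2.85), Rgn (-2.74) and Slc1a2 (-2.51) lower and Slc13a3 (2.66) higher. Camera gave adjusted p = 0.00445, and adjusted p = 0.167 with an estimated correlation.

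Of 19 oncofetal and tumour marker genes 16 rose and 1 fell in HCC (16 and 1 adjusted over the list alone; median 3.01), with camera adjusted p = 1.03e-08 and adjusted p = 0.056 with an estimated correlation. Female-biased liver genes rose in 7 of 10 (7 adjusted over the list alone; median 2.10), with Cyp2b9 (6.78) and Cyp2b13 (at least 18.3-fold), whose probes may read copies, and the peroxisomal transporter gene Abcd2 (4.29). Camera gave adjusted p = 0.00326, and adjusted p = 0.167 with an estimated correlation. Cell division genes rose in 16 and fell in 3 of 27 (16 and 4 adjusted over the list alone; median 0.93), with the mitotic genes Prc1 at least 8.4-fold, Cdc20 at least 4.87-fold and Plk1 at least 3.4-fold higher and Birc5 at 1.80. Camera gave adjusted p = 0.00466, and adjusted p = 0.577 with an estimated correlation. p53 targets and damage response genes rose in 8 of 19 (8 adjusted over the list alone; median 0.77), with the cell cycle inhibitor gene Cdkn2b at least 47.6-fold, Phlda3 at least 8.21-fold and the inhibitor gene Cdkn2a at least 5.4-fold higher and Zmat3 at 1.62. Camera gave adjusted p = 0.00466, and adjusted p = 0.22 with an estimated correlation.

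Progenitor-associated genes rose in 10 and fell in 2 of 15 in HCC (11 and 2 adjusted over the list alone; median 1.19), with Tnfrsf12a (2.68), Sox4 (at least 3.76-fold), Icam1 (2.45), Dlk1 (at least 2.98-fold) and Sox9 (1.81) higher. Camera gave adjusted p = 0.00201, and adjusted p = 0.167 with an estimated correlation. Cd44, an adhesion receptor, had a log2 change of 0.68 (SE 0.27) that did not pass (adjusted p = 0.0532). YAP targets rose in 6 and fell in 1 of 9 (6 and 1 adjusted over the list alone; median 1.70), including Ccn2 (3.74), Nt5e (3.65), Axl (2.80) and Amotl1 (2.36), with camera adjusted p = 0.00791 and adjusted p = 0.167 with an estimated correlation. Adhesion and junction genes rose in 11 of 18 (11 adjusted over the list alone; median 1.00), with E-cadherin Cdh1 (3.27), Cldn1 (2.96), Cldn3 (2.57) and F11r (2.08), and camera adjusted p = 0.00037, or adjusted p = 0.167 with an estimated correlation. Endoplasmic reticulum stress genes rose in 8 and fell in 1 of 19 (8 and 1 adjusted over the list alone; median 0.74), with Trib3 at 3.98 and the chaperone genes Pdia6 (1.74), Pdia4 (1.13) and Hspa5 (1.07), and camera adjusted p = 0.00791, or adjusted p = 0.481 with an estimated correlation. NF-kB targets rose in 10 and fell in 1 of 16 (11 and 1 adjusted over the list alone; median 0.65), with Vcam1 (3.32), Ccl4 (at least 4.59-fold) and Ltb (at least 3.69-fold), and camera adjusted p = 0.00201, or adjusted p = 0.167 with an estimated correlation. Interferon-stimulated genes rose in 10 of 26 (9 adjusted over the list alone; median 1.37), with Igtp (2.09), Gbp2 (2.02), Tap1 (1.99) and Ifit2 (1.83), and camera adjusted p = 0.00201, or adjusted p = 0.572 with an estimated correlation.

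Markers of other liver cells were higher in HCC beside these groups. Which cells carry the changes in HCC given above was not tested, so they cannot be assigned to the malignant cells alone. Endothelial markers rose in 18 of 19 (18 adjusted over the list alone; median 1.88), with Emcn (3.59), Cdh5 (2.99), Lyve1 (2.61) and Ptprb (2.59), camera adjusted p = 2.81e-08 and adjusted p = 0.22 with an estimated correlation. Macrophage markers rose in 14 and fell in 1 of 18 (14 and 1 adjusted over the list alone; median 2.15), with Cd14 (4.01), Mpeg1 (3.56), Laptm5 (3.29) and Lyz1 (2.88), camera adjusted p = 6.54e-05 and adjusted p = 0.428 with an estimated correlation. Stellate cell and fibroblast markers rose in 12 of 17 (13 adjusted over the list alone), with a median of 1.42, or 0.83 with undetected genes at their bound. Acta2, smooth muscle actin, detected on 1 of 3 normal arrays, rose by 5.14 (SE 0.35), Reln by 4.54, Sparc by 4.36 and Bgn by 2.58. Camera gave adjusted p = 4.99e-06, and adjusted p = 0.167 with an estimated correlation. T and NK cell markers rose in 3 of 6 (3 adjusted over the list alone; median 0.64), with Ccl5 at least 6.03-fold, Cd3g at least 1.18-fold and Cd8b1 at 0.78, camera adjusted p = 0.0479 and adjusted p = 0.415 with an estimated correlation. Cd8b1 already stood at 9.47 in normal hepatocytes, where Ccl5 and Cd3g were not detected, so it need not read T cells here.

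The remaining lists did not pass in HCC, where 21 lists were called. Hepatocyte plasma protein and transcription factor genes had 2 higher and 6 lower of 21 (2 and 6 adjusted over the list alone; median 0.01, mean -0.19 and test downward; camera adjusted p = 0.743), and IL-6 and acute phase genes 6 higher and 13 lower of 31 (7 and 13 adjusted over the list alone; median -0.28; adjusted p = 0.28). Medians were 0.59 for NRF2 and glutathione genes, 0.49 for cholesterol synthesis, 0.31 for fatty acid synthesis, 0.27 for hypoxia-inducible genes, 0.24 for complement and coagulation factors and -1.28 for periportal genes. They were 0.19 for housekeeping genes, 0.08 for immediate early genes, -0.00466 for glycolysis, whose mean was 0.20 and test upward, and -0.20 for bile duct markers, whose mean was 1.55 and test upward, with Tspan8 and Sox9 among its 5 measured members. B cell, neutrophil and red cell markers had 1, 3 and 2 measured members and were not tested as lists; their medians were 0.32, 0.12 and 0.27. Of these lists periportal genes passed downward with median scaling (adjusted p = 0.00406), cyclic loess (0.0451), the submitters' normalized values (0.0221) and no detection filter (0.0451), and IL-6 and acute phase genes downward with median scaling (0.0206). NRF2 and cholesterol synthesis genes passed upward without the filter (adjusted p = 0.0311 and 0.0168). Scaling changed the balance of calls: with median scaling, which moved the median of all genes to 0.18, 70.7% of called genes were higher, with cyclic loess 56.6% and with the submitters' normalized values 58.8%, against 47% here.

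Aggregate cells were compared with non-aggregate premalignant hepatocytes to find what sets the aggregated cells apart. Tumour marker genes were higher in aggregates. Tspan8 rose by 3.40 on the log2 scale (SE 0.43, 10.6-fold, adjusted p = 0.00352), Akr1c18 by 3.37 (SE 0.40, adjusted p = 0.00315), Gpc3 by 2.64 (SE 0.49, adjusted p = 0.0308) and Ly6d by 2.03 (SE 0.21, adjusted p = 0.00232). Esm1, an endothelial proteoglycan gene, rose by 2.79 (SE 0.42), Cd63 by 2.63 (SE 0.28), the protease inhibitor gene Slpi by 2.59 (SE 0.35), Reln by 2.52 (SE 0.43) and Gldn by 2.50 (SE 0.39). Ly6d, Esm1, Slpi, Afp and Cd44 were detected on only 2 of the 3 non-aggregate arrays. Afp had a change of 2.24 (SE 0.65) that did not pass (adjusted p = 0.177), as did Cd44 at 0.58 (SE 0.27, adjusted p = 0.72), Sox9 at 0.50 (SE 0.46) and Cyp2e1 at 0.03 (SE 0.16). Epcam, Il6, Krt19 and Lin28b lay below the detection filter, and no probe was named Ggt1 or H19.

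**Figure D1:**
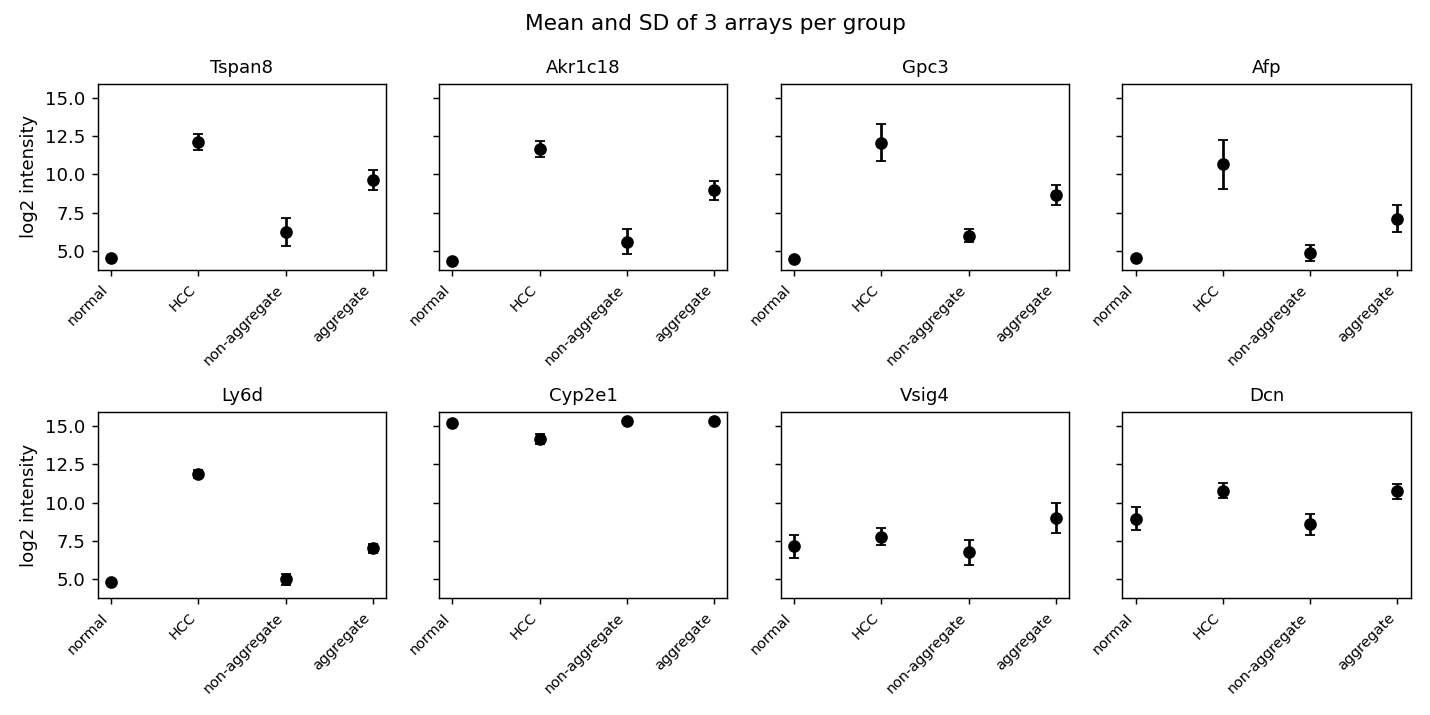
Mean log2 intensity of 8 genes in the 4 groups, with bars for the SD of 3 arrays. Gpc3 stood at 4.48 in normal hepatocytes, where it was not detected, 5.99 in non-aggregates, 8.63 in aggregates and 12.07 in HCC; groups of different chips are drawn together although chip and group cannot be told apart.

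In limma, 81 genes rose and 0 fell in aggregates, while 609 were higher and 155 lower at an unadjusted p under 0.05. With the replicate number as a block, 90 rose and 0 fell, and with only the arrays of these groups in the fit 222 rose and 3 fell. Falls were also called with array weights (351 higher, 28 lower) and with the block on only these arrays, an alternative chosen after seeing the data (447 higher, 42 lower). The count depended on single arrays: it was 16, 32 and 32 without non-aggregate replicates 1, 2 and 3, and 39, 139 and 19 without aggregate replicates 1, 2 and 3.

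Of 19 oncofetal and tumour marker genes 5 rose in aggregates, and 6 with the replicate block (9 adjusted over the list alone), with a median of 1.19, camera adjusted p = 1.21e-17, and adjusted p = 0.0139 with an estimated correlation. Beside them, macrophage markers rose in 2 of 18, and in 8 with the replicate block (17 adjusted over the list alone; median 1.78; camera adjusted p = 1.77e-28, and adjusted p = 0.0452 with an estimated correlation). They were Adgre1, a macrophage surface receptor gene, at 2.23 (SE 0.45) and the scavenger receptor gene Marco, at least 1.46-fold. Endothelial markers rose in 5 of 19, and in 0 with the block (16 adjusted over the list alone; median 1.29; camera adjusted p = 2.93e-28, and adjusted p = 0.0452 with an estimated correlation). Their largest were Ramp2 (1.57; adjusted p = 0.0274, blocked 0.0523), Lyve1 (1.54; 0.0426, blocked 0.0616), Cdh5 (1.39; 0.0478, blocked 0.0616) and Ptprb (1.33; 0.0292, blocked 0.0523). Stellate markers rose in 3 of 17 (2 with the block), namely Reln, the matrix gene Dcn (2.17) and Lrat (1.43; adjusted p = 0.0406, blocked 0.0616; detected on 1 of 3 non-aggregate arrays). That list had 10 higher adjusted over the list alone, a median of 0.71, or 0.54 with undetected genes at their bound, camera adjusted p = 1.54e-13, and adjusted p = 0.0452 with an estimated correlation.

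Female-biased genes shifted up in aggregates with a median of 1.03 (0 of 10 called, 2 with the block, 3 adjusted over the list alone; camera adjusted p = 7.75e-06, and adjusted p = 0.0452 with an estimated correlation). NF-kB targets did so with a median of 0.43 (0 of 16 called, 1 with the block, 3 adjusted over the list alone; adjusted p = 5.54e-07, and adjusted p = 0.0452 with an estimated correlation), and YAP targets with 0.30, or 0.17 with undetected genes at their bound (0 of 9 called, 1 with the block, 3 adjusted over the list alone; adjusted p = 0.000615, and adjusted p = 0.0452 with an estimated correlation). Cholesterol synthesis genes, with 0 of 15 called and 0 adjusted over the list alone, had a median of 0.45 (adjusted p = 5.21e-05, and adjusted p = 0.43 with an estimated correlation). Progenitor-associated genes had 0 of 15 called, 1 adjusted over the list alone and a median of 0.26 (adjusted p = 0.0113, and adjusted p = 0.194 with an estimated correlation). Cell division genes had 0 of 27 called, 0 adjusted over the list alone and a median of 0.24 (adjusted p = 0.0178, and adjusted p = 0.856 with an estimated correlation). NRF2 and glutathione genes had 0 of 26 called, 0 adjusted over the list alone and a median of 0.13 (adjusted p = 0.0368, and adjusted p = 0.856 with an estimated correlation). In all 11 lists were called, all upward, but 4 of the 10 splits of these 6 arrays, the real one included, called as many lists. Downward calls appeared under other settings: urea cycle and amino acid genes passed without background correction (adjusted p = 0.0394), with median scaling (0.00341), with cyclic loess (0.00721) and with the submitters' normalized values (0.00404), and fatty acid oxidation genes with the last (0.0311).

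The other lists, those of liver metabolism among them, did not pass in aggregates here. Hepatocyte plasma protein and transcription factor genes had a median of 0.00307, a mean of -0.03, a test pointing down and camera adjusted p = 0.964. Cytochrome P450 genes, with 1 called, 0 with the block and 1 adjusted over the list alone, had a median of -0.01, a mean of 0.01, a test pointing down and adjusted p = 0.931, and urea cycle and amino acid genes -0.15 and adjusted p = 0.0595. Medians were -0.08 for bile acid genes, -0.11 for gluconeogenesis, -0.15 for fatty acid oxidation, -0.08 for pericentral genes and -0.12 for male-biased genes. They were 0.14 for fatty acid synthesis, 0.09 for interferon-stimulated genes, 0.02 for p53 targets, 0.06 for endoplasmic reticulum stress, 0.03 for complement, 0.07 for adhesion, -0.06 for hypoxia (mean 0.02) and 0.06 for bile duct markers. T and NK markers had a median of 0.16, B cell, neutrophil and red cell markers, untested, 0.18, 0.18 and 0.73, and housekeeping genes -0.00641. For IL-6 and acute phase genes (-0.00539), immediate early genes (-0.00471), glycolysis (-0.09) and periportal genes (-0.05) the median was below 0 while the mean and test pointed up.

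The genes raised in aggregates were largely those raised in HCC. Of the 81 genes called in aggregates 78 were also called higher in HCC, where independent lists would share 18.7, and 0 were called the opposite way. Their median log2 change was 2.98 in HCC and 1.49 in aggregates. Across all genes, which are not independent replicates, Pearson r was 0.66 and Spearman rho 0.55, and 71.3% of genes had the same sign. These comparisons share no arrays, but the fit takes 1 spread per gene from all 12 arrays for both. Their calls are thus not independent, and 18.7 may be too low for chance. The shared count was 143 without normal replicate 3, 119 and 135 without HCC replicates 1 and 2, 16, 32 and 31 without non-aggregate replicates 1, 2 and 3, and 39, 126 and 19 without aggregate replicates 1, 2 and 3.

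**Figure D2:**
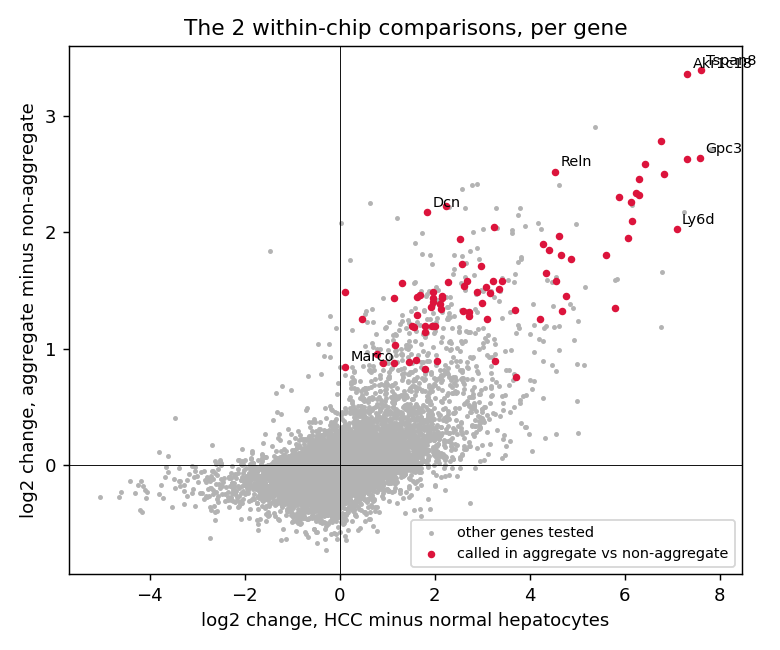
Each point is a gene, with its log2 change in HCC against normal hepatocytes on the horizontal axis and in aggregates against non-aggregates on the vertical axis; red points are the 81 genes called in aggregates. Spink1 lies at 7.82 and 2.71, and Dcn at 1.84 and 2.17. In limma the change of Spink1 in aggregates did not pass (adjusted p = 0.0637) but passed with the replicate block (adjusted p = 0.000509). Genes not detected in a group are drawn at their background values.

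The change in aggregates was set against that in HCC by a test of the difference itself. Spink1 had a difference of log2 changes of -5.11 (SE 0.86), Cyp2a4 of -5.07 (SE 0.80) and Cyp2b9, whose probe may read copies and was detected on 2 of 3 normal arrays, of -5.12, each more raised in HCC. The milk casein gene Csn3 (-5.57) and Ly6d (-5.07) were also called, but neither was detected on any normal array, and Csn3 was detected on 1 and Ly6d on 2 of 3 non-aggregate arrays, so their differences rest on values not above background. Sult2a8 (4.78), Gadd45g (4.38), Hsd3b5 (4.07), Mfsd2a (4.06) and Cyp4a12b (4.28; may read copies) were lowered in HCC beyond any change in aggregates. In all 2214 genes differed, 1065 with a more positive and 1149 with a more negative change in aggregates. With median scaling these were 433 and 1863, with cyclic loess 829 and 1260, and with the submitters' normalized values 800 and 1244. Cytochrome P450 genes differed by a median of 1.40 (adjusted p = 3.06e-07, and adjusted p = 0.00897 with an estimated correlation), the only list of 19 called whose call held so. Male-biased genes differed by 1.91 (adjusted p = 1.53e-07, and adjusted p = 0.197 with an estimated correlation) and oncofetal genes by -2.46 (adjusted p = 3.56e-08, and adjusted p = 0.0742 with an estimated correlation), while macrophage markers did not pass (median -0.34, adjusted p = 0.65).

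Comparisons of premalignant cells with normal hepatocytes and HCC run across chips, so chip and group cannot be told apart in them. Against normal hepatocytes, aggregates had more Cyp2a4 (5.64, SE 0.57), Tspan8 (at least 27-fold) and Akr1c18 (at least 16.9-fold), and less Mt2, a metallothionein (-4.06, SE 0.39), Ppp1r3g (-3.34) and the acute phase gene Saa2 (-2.87; may read copies). Non-aggregates had more Cyp2a4 (3.46, SE 0.57), Tsc22d1 (2.36) and Dclk3 (2.24), and less Mt2 (-4.46; detected on 1 of 3 non-aggregate arrays), Mt1 (-3.53) and Igfbp1 (-2.91) than normal hepatocytes. Against HCC, aggregates had more Sult2a8 (4.77), Cyp4a12b (4.70; may read copies) and Car3, a carbonic anhydrase (4.60), and less Csn3 (-5.21; detected on 2 of 3 aggregate arrays), Ly6d (-4.87) and Igfbp1 (-4.86). The counts were 539 (354 higher, 185 lower) for aggregates against normal, 159 (83 and 76) for non-aggregates against normal and 3738 (1881 and 1857) for aggregates against HCC. Scaling changed their balance: with median scaling they were 489 higher and 112 lower, 95 and 41, and 1010 and 2548. Against HCC they were 1542 and 2205 with cyclic loess and 1505 and 2215 with the submitters' normalized values. The first was 301 and 351 without normal replicates 1 and 2, and 224, 347 and 163 without aggregate replicates 1, 2 and 3; the second was 59, 66 and 368 without normal replicates 1, 2 and 3 and 54, 20 and 50 without non-aggregate replicates 1, 2 and 3.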

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

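The tests of cell content, tumour carry-over, female mice and hepatocyte share were chosen after the result was seen; those of a fixed tumour share, of gene copies and of the splits were chosen before.

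The changes in HCC and in aggregates differed by the test of the difference itself for 2214 genes, and for cytochrome P450 genes by a median of 1.40 on the log2 scale. Of 100 joint splits of both chips drawn from 200, 10 called at least 2214 genes and the highest other called 4232, so chance was not excluded by this count; all 10 of them keep HCC and normal apart, which points to the HCC effect as the structure behind them. For the correlation of the comparisons, 1 of 100 joint splits, the real one, reached 0.66, against 0.62 for the highest other (jackknife SE of r over arrays 0.05). Over all drawn splits that share lies under 0.05, but all except 10 of them mix HCC with normal arrays and so remove the HCC effect. Those 10 are too few for a share under 0.05, so chance was not excluded. Among those 10 the highest other was 0.37. Some joint splits break the same-numbered pairs of aggregate and non-aggregate arrays; among the 40 that part all 3 pairs as the real one does, 1, the real one, reached it, and the highest other was again 0.62. The others of these differ from it in mixing HCC with normal arrays, in exchanging members within same-numbered pairs, or in the direction of a comparison. The remaining comparisons have 10 splits each, too few for a share under 0.05: in each, 1 split, the real one, gave as many genes, with 5218, 81, 539, 159 and 3738 calls against a highest other of 0. Of the 9 other splits of the aggregate comparison, 3 part every same-numbered pair as the real one does, and limma called 0 genes in them. For lists, the HCC comparison called 21 against a highest other of 17, and the aggregate comparison 11 against 12, with 4 of 10 splits calling as many.

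Macrophage, endothelial and stellate markers were higher in aggregates. A lower share of hepatocyte RNA alone would raise these lists alike. Among members detected on all non-aggregate arrays the macrophage mean exceeded the endothelial mean by 0.60 (SE 0.15 over genes and 0.12 over the 3 pairs, which gave 0.83, 0.45 and 0.52). These lists were picked as the highest and lowest means, with stellate markers between at 1.67 (SE 0.39 over 5 members). The 95% interval over pairs, 0.60 ± 0.50, does not allow for that choice, so a lower share was not excluded. T and NK markers had too few such members. Carry-over of tumour tissue as a part of the rise stays open. Macrophage markers in aggregates lay at a median of -0.50 relative to the higher of HCC and non-aggregates, as carry-over allows. But 6 of these 18 markers had an aggregate mean above both. Shares of the HCC level were taken for 33 markers at least 2-fold higher in HCC than in non-aggregates. Markers called at least 16-fold higher in HCC than in normal hepatocytes were left out, among them Cd14, Acta2, Sparc and Reln. Their log2 changes were 4.01, 5.14, 4.36 and 4.54 in HCC and 1.13, 0.86, 1.59 and 2.52 in aggregates. Leaving them out can widen both gaps given next and lower the ratio of shares after them. The shares of the 33 markers exceeded those of tumour genes kept at 16-fold by 41.5 points (SE 13.6 over pairs). They exceeded those of other genes matched on HCC excess by 37.1 (SE 13.3 over pairs, 33 of 33 above). Both 95% intervals over 3 pairs include 0. A further test of shares, run only after those had not decided, covered the same 33 markers. If levels compare across chips, it argued against carry-over as their whole rise. There 157 genes at least 4-fold lower in HCC showed a mean of 0.36 times the share that the markers need (SE 0.10 over pairs, which gave 0.21, 0.56 and 0.31). Carry-over predicts 1, and the 95% interval ends at 0.81. These shares and the median of -0.50 set HCC against premalignant cells of the other chip, where chip and group cannot be told apart. The markers also came from lists already called higher in aggregates, which can lower this ratio. More macrophages, endothelial and stellate cells in the aggregate samples, or a change within such cells, stay open, as the 100% of 47 detected members with a positive change restates that these lists were higher and decides nothing; 14 of 18 macrophage, 15 of 19 endothelial and 5 of 17 stellate markers were also detected on all 3 normal hepatocyte arrays.

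The genes higher in both HCC and aggregates stayed open to technical explanations. Without marker genes, their median excess over normal hepatocytes differed by -0.14 (SE 0.16) from that of macrophage markers, so non-parenchymal cells could carry part of them. Of the 78 genes, 20 were detected on no normal array. These excesses, and the shares of tumour tissue below, run across chips, where chip and group cannot be told apart. A fixed share of tumour tissue predicts 1 share for every gene, and the variance of the share between 74 tumour genes was 3.15 times that expected from the arrays, between the bounds set before, with shares from 2.74% to 15% (10th and 90th percentiles), so this cannot be told apart here from tumour-like expression in the aggregated cells. Leaving out the non-parenchymal marker genes, an alternative chosen after seeing the data, gave Pearson r of 0.66. These are few of the 10641 genes, so r could hardly move, and this decides nothing about such cells. Whether the genes higher in both reflect the premalignant aggregated cells themselves, the difference the design names, stays open and untested.

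Male-biased genes fell and female-biased genes rose in HCC at the preset correlation. Samples wholly of female mice were argued against by the Y-linked gene Eif2s3y, detected on 3 of 3 HCC arrays, and the labels state male mice; its log2 change of -1.20 in HCC (adjusted p = 0.0026) was not explained. A lower share of hepatocyte RNA was argued against by hepatocyte plasma protein and transcription factor genes, whose mean lay 2.29 (SE 0.39 over genes and 0.42 over arrays) above that of male-biased genes. Outside the copy families named above, the male-biased median was -2.08 over 9 genes and the female-biased median 2.02 over 7. This argued against copies read within those families as the whole shift. Other families of related genes were not set apart, so copies read among them stay open. A loss of male-biased expression in the tumour cells stays open as untested, and neither list's call held with an estimated correlation (adjusted p = 0.167 and 0.167).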

How the results depend on the processing

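No named gene's change and no list's shift that passed with the main processing or with an alternative reversed its direction between them. Sign changes of values that passed with neither were not counted. Named genes were not checked in this way with each probe by itself. List shifts were not checked with array weights, separate normalization of the chips, only the groups compared or an array left out. The balance of higher and lower calls turned with scaling. Of 2356 log2 changes of named genes under the alternatives, 2219 kept their side of the threshold, 129 fell short of it and 8 newly passed it; of 526 list shifts these were 482, 32 and 12. With an estimated correlation 1 list was called in HCC and 7 in aggregates, against 21 and 11. The aggregate count of 81 was 26 without background correction, 215 with median scaling, 153 with cyclic loess, 40 with the deposited normalized values, 27 without the detection filter, 225 with only the groups compared and 379 with array weights; genes shared with HCC were then 26, 209, 148, 40, 26, 206 and 326. Array weights called 28 of the aggregate genes lower. The HCC count of 5218 moved the other way, to 3868 with only the groups compared and 4295 with array weights. The main fit shares 1 spread per gene over all groups. The median SD between replicates was 0.26 in HCC and 0.22 in normal hepatocytes, against 0.15 in non-aggregates and 0.16 in aggregates. The replicate block with only the arrays of chip 2, an alternative chosen after seeing the data, called 489 genes, 42 of them lower, and shared 79 of the 81. The planned replicate block gave 90 genes in aggregates and called 11 lists there; the numbers did not pair the arrays of HCC and normal hepatocytes (r of -0.01, 0.12 and 0.10 for same numbers), where the block gave 5568, nor across chips, where it gave 481, 150 and 3774, and the difference of changes 2774. Each probe tested by itself, with more tests by construction, gave 9095 calls in HCC, 3568 for the difference and 6316 for aggregates against HCC. A log2 change of at least 1 as well, a stricter rule by construction, left 2408 in HCC, 298 and 88 for aggregates and non-aggregates against normal and 1645 for aggregates against HCC. For non-aggregates against normal only the groups compared gave 62 and array weights 516, and array weights gave 1035 for aggregates against normal. Except where the construction shows it, the cause was not tested. Leaving out each array gave 4410 to 5204 calls in HCC, 16 to 139 in aggregates, 1556 to 2674 for the difference, 163 to 604, 20 to 368 and 2778 to 3986 across chips in the order above, 16 to 143 shared genes, and Pearson r of 0.62 to 0.67. Signal over background limits dim genes: 33.9% to 43% of probes were detected per array.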

Other observations

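The genes in this part were chosen after their values were seen. Some macrophage genes changed differently in HCC and aggregates, while as a list they did not pass that test (median difference -0.34, 2 of 18 higher and 2 lower, limma camera adjusted p = 0.65). Adgre1 rose by 2.23 in HCC and 2.23 in aggregates (adjusted p of the difference = 0.996). Cd14 and Mpeg1 rose in HCC by 4.01 and 3.56 on the log2 scale and had changes of 1.13 and 0.81 in aggregates that did not pass (adjusted p = 0.247 and 1; 0.358 and 0.126 with the replicate block), Cd14 being detected on 2 of 3 non-aggregate arrays, and their changes differed (adjusted p = 0.00269 and 0.0173). Marco, a Kupffer cell receptor gene, was detected on 3 of 3 aggregate arrays, 1 HCC array and no array of the other groups. Clec4f and Vsig4, markers of resident Kupffer cells, had 1.76 and 2.26 in aggregates (adjusted p = 0.185 and 0.0689; 0.0644 and 0.0338 with the replicate block, with which Vsig4 passed) and 0.22 and 0.64 in HCC, which did not pass, nor did their difference (adjusted p = 0.159 and 0.146). Among stellate genes, Sparc, of activated cells, differed between the comparisons by -2.77 (adjusted p = 0.00206), while Dcn rose in both and its changes did not differ at the threshold (adjusted p = 0.726).

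Within lists that did not pass in HCC, members moved in opposite directions. Albumin, Alb, rose by 1.69, while the transcription factor genes Nr1i2 (-1.47), Prox1 (-1.27), Cebpa (-1.07), Nr1i3 (-1.03), Foxa1 (-0.72) and Hnf4a (-0.61) fell. Among acute phase genes Lcn2 rose by 4.24, and Saa1 (-3.66; may read copies), Saa3 (-2.01), the iron hormone gene Hamp (-1.82) and Socs3 (-1.71) fell. Among NRF2 and glutathione genes Cbr3 (5.79) and Abcc4 (4.92; detected on 2 of 3 normal arrays) rose, and Ces1g (-2.27) fell. Cdkn2b stood at 4.61 in normal hepatocytes and 4.59 in non-aggregates, where it was not detected, at 6.19 ± 0.19 (SD, n = 3) in aggregates and at 10.45 ± 1.05 in HCC; its change in aggregates did not pass in limma (adjusted p = 0.0689, or 0.123 with the block).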
